A study of Mus musculus with 8 samples.

How the data were processed

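Gene expression was measured by RNA sequencing in 8 libraries of mouse PyMT mammary tumour cells, that is, cells from mammary tumours driven by the polyoma middle T oncogene. The cells had been separated by fluorescence-activated sorting into CD90-positive (CD90pos) and CD90-negative (CD90neg) populations. CD90 is the surface protein encoded by Thy1. Each population was either left untreated (control) or treated with interferon gamma (IFNg) at 10 IU per ml for 24 h, per the labels. The 4 groups held 2 libraries each, and the labels gave every group a library with the letter A and a library with the letter B. Per the labels' protocols, RNA was isolated with a kit for small inputs and libraries were made with a stranded, poly(A)-selecting mRNA kit.

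The authors deposited 1 table of normalized read counts per gene (a signal that is never negative), with 12964 genes and 8 columns, and none of its columns belonged to other samples. STAR and HTSeq, with no version, and the builds mm10 and GRCm38 are named in the submitters' processing notes. How the table was filtered is not given in the sources used here. The lowest value that any gene reached at its maximum was 43.4 normalized reads, so genes with low values in all libraries are not represented. The values of each column were whole multiples of 1 step per library, which is what read counts divided by a size factor give. Dividing each column by its step gave whole reads for 100% of the values within a tolerance of 0.001. The recovered reads summed to between 31243646 and 40899909 per library. A floor of 3 reads corresponded to between 2.55 and 3.37 normalized reads. Counting error alone is 31.6% of the value at 10 reads. Because reads without molecular identifiers are not independent molecules, floors and counting errors cover counting error only. Gene symbols were matched to GENCODE vM21 for identifiers and coordinates on GRCm38, and 2 symbols occurred more than 1 time in the table.

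Values were analysed as log2(normalized reads + 1). The 12962 genes at 10 or more normalized reads in at least 2 libraries were tested, which left out 2 genes. Each fold change is on the log2(value + 1) scale, and for genes near 0 in control libraries its size depends on the pseudocount. Differences were tested with limma 3.58.1 (R 4.3.3), using 1 mean per group, all 8 libraries and a trend of the variance on the mean. Tests were two-sided and adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. All adjusted p-values of single genes come from this limma fit unless another tool or fit is named. The deposited values turned out to be normalized reads and not raw counts, so the count test foreseen for raw counts was not used as the main test. It was run on the recovered reads as an alternative added after the data were examined, with edgeR 4.0.16 (quasi-likelihood test, TMM factors) and DESeq2 1.42.0 (Wald test). The 5 comparisons were the IFNg effect in each population, CD90pos against CD90neg cells in control and in IFNg libraries, and the interaction, which is the IFNg effect in CD90pos cells minus that in CD90neg cells.

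A second fit with the letter A or B as a block had been listed before the data were examined. The labels do not say what the letters stand for. Libraries with the same letter deviated together: the differences between A and B correlated across genes with coefficients from 0.779 to 0.920 over the 6 pairs of groups. The first principal component held 51.5% of the variance and separated the letters, and the second held 34.4% and separated control from IFNg libraries. Such an orientation of the letters arises by chance in 1 of 8 arrangements, or 12.5%. The letters were taken to pair the samples because of these correlations, although a share of 12.5% does not settle it. Sample numbers in the titles also run consecutively within each letter, across the 4 groups. Values from the blocked fit are given beside results that they change. The fit without the block stayed the main one, as set beforehand. It counts the shared difference between the letters as spread between the libraries of a group, so genes can miss its threshold for that reason. The residual degrees of freedom were 4 (2.06 prior degrees) without and 3 (3.77 prior degrees) with the block. Nothing in the labels says that the libraries came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

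Gene lists fixed before the data were examined were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists within a comparison. Camera with an estimated correlation and limma's fry were run beside it. Of 30 lists, 28 had at least 5 measured members. Endothelium and pericyte markers, with 4 of 15 measured (Flt1, Eng, Mcam and Notch3), and histone transcripts, with 3 of 14 measured, were not tested. Members of a list were counted as called over all genes tested and also with p-values adjusted over the list alone.

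Named genes followed a rule fixed beforehand. Thy1, Ifngr1, Ifngr2, Irf1 and Cd274 were always named, and some results that the rule takes are not reported here. For each comparison, the 10 called genes with the largest change in each direction were taken, provided that the groups of libraries did not overlap and that the higher group lay above the median of all genes, leaving out predicted gene models, clone names, pseudogenes and immunoglobulin or T cell receptor segments. For the interaction the adjusted p took the place of the condition on overlap. Where fewer than 3 passed, the 3 genes with the smallest p were taken and are said to miss the threshold. Lists that are described name up to 4 called members with the largest change, or the 2 with the smallest p where none was called. Some of the genes picked in the blocked fit are also named, as such, and that choice was made after the data were examined. There the same sign in letters A and B took the place of the condition on overlap, so the groups of libraries may overlap. Where genes were taken by the smallest p, neither of these conditions applied. Reads may be divided between near-identical or overlapping genes in Tgtp1 and Tgtp2, H2-Q6 and H2-Q7, the Gbp and Prl2c families, and Olfr56, which overlaps Tgtp1 and Tgtp2, so the values of these genes are uncertain.

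To measure trends with transcript length and GC content, each gene was given the length and GC content of its longest GENCODE transcript (Biostrings 2.70.1), which was possible for 12947 genes (99.9%). The trend was removed from each library with smooth terms for length and GC content (mgcv 1.9.3). Other alternatives were pseudocounts of 0.5 and 5, no filter, a filter at 50 normalized reads, quantile normalization, median centring, a prior variance without the trend, a robust prior, only the 4 libraries of a comparison, a required change of at least 2-fold, and the omission of each library in turn.

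The tests were run on simulated counts drawn for the 12962 genes, with 100 genes changed by 1 and 100 by 2 on the log2 scale. Means were those of each letter over the 4 groups, and dispersions came from a blocked edgeR fit. The simulated letters thus differed equally in all groups, as the block assumes, which favours the blocked fit. How it performs where the letters differ unequally between groups was not checked. For the IFNg effect in CD90pos cells, the fit without a block recovered 0% of genes changed by 1 and 21% of genes changed by 2, and the blocked fit recovered 55% and 92%, with 6.37% of its calls false. For CD90pos against CD90neg control cells these values were 1% and 32% without and 49% and 92% with the block, with 14.5% of the blocked calls false. For the interaction they were 0% and 0% without and 17% and 81% with the block, with 3.92% false. A simulated list changed by 1 in CD90pos IFNg libraries had a camera adjusted p of 7.4e-25, and 0 of the other lists were called. The simulated genes varied independently of each other, so this check could not show false calls of lists whose members vary together. Removal of a simulated length trend in the control comparison lowered the false calls from 327 to 15.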

Results

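RNA sequencing profiles were compared between CD90pos and CD90neg PyMT mammary tumour cells, each with and without 24 h of IFNg, with 2 libraries per group (A and B). IFNg is the cytokine through which activated T cells and NK cells induce antigen presentation and antimicrobial genes. CD90pos control libraries A and B held 31243646 and 32246195 recovered reads and CD90pos IFNg libraries 35952019 and 35144542. CD90neg control libraries held 32852037 and 32772045 and CD90neg IFNg libraries 39304070 and 40899909. The 10 highest genes took between 4.83% and 6.53% of the reads of a library. Mitochondrially encoded genes took 2.31% in CD90pos control A and 0.670% in CD90pos control B, the highest and lowest of the 8 libraries.

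Thy1, the gene of the sort marker CD90 (GRCm38 chromosome 9, 44043384 to 44048579), followed the labels in every library. It was at 889 ± 857 normalized reads in CD90pos control cells and 18.6 ± 2.79 in CD90neg control cells (SD, n = 2), with 283 and 1495 against 20.6 and 16.6 in letters A and B. In IFNg libraries it was at 3066 ± 1231 against 60.6 ± 6.95 (SD, n = 2). As the sort marker it checks the labels and is no finding. The largest axis of variation separated the letters, as the plot of principal components shows.

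**Figure D1:**
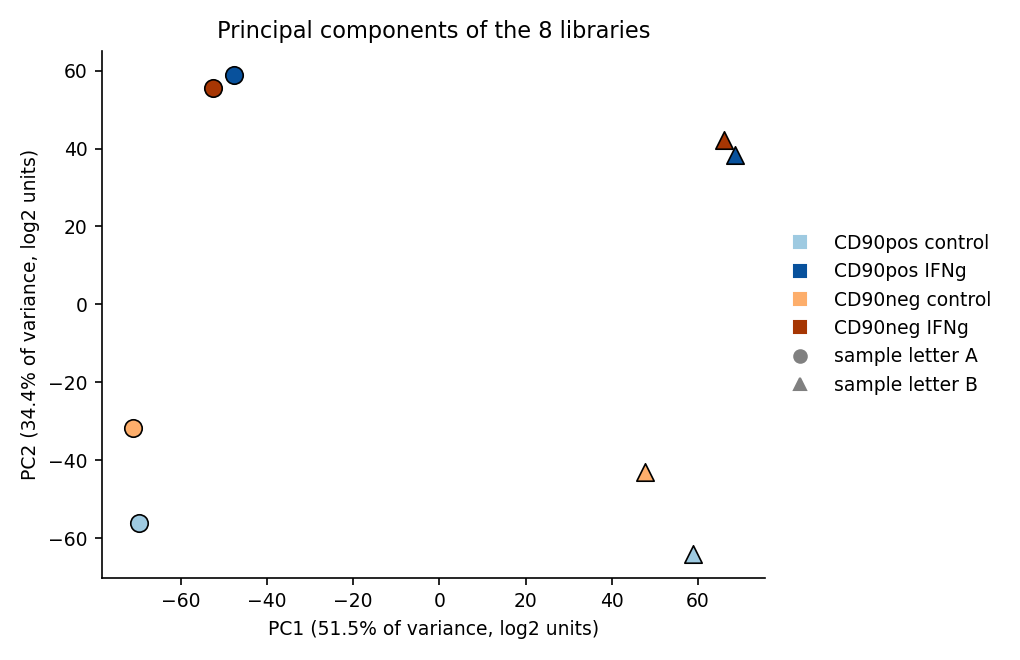
The first principal component (x axis, 51.5% of the variance, log2 units) and the second (y axis, 34.4%) are plotted for the 8 libraries, coloured by group, with circles for letter A and triangles for letter B. Letter A libraries lie between -71.2 and -47.7 on the first component and letter B libraries between 47.7 and 68.6, and all IFNg libraries lie above all control libraries on the second.

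IFNg strongly raised interferon-response genes in CD90pos cells. Of the genes taken by the naming rule, the guanylate-binding protein Gbp4, the T cell chemokine Cxcl9, the immunity-related GTPase Tgtp2 and the inducible nitric oxide synthase Nos2 had the largest increases. Cxcl9 was at 48.2 and 5.61 normalized reads in the control libraries and 127120 and 75388 in the IFNg libraries, and Nos2 went from 8.22 ± 10.0 to 23408 ± 8142 (SD, n = 2). Among called genes that met the naming rule, the largest decreases were in Ndufa4, a mitochondrial respiratory chain gene, and Cav2, a caveolin. The carbonic anhydrase Car2 fell from 2658 ± 61.1 to 816 ± 24.6 normalized reads (SD, n = 2).

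In total 546 of 12962 genes were called, 273 higher and 273 lower, and all 546 were among the 3578 called in the blocked fit (1815 higher, 1763 lower). Gbp4 (GRCm38 chromosome 5, 105115767 to 105139586) had a log2 fold change of 13.12 (SE 2.19, adjusted p = 0.0374), Cxcl9 (chromosome 5, 92321347 to 92328079) of 12.41 (SE 1.69, adjusted p = 0.0318), Tgtp2 of 12.02 (SE 1.34, adjusted p = 0.0212) and Nos2 (chromosome 11, 78920787 to 78960254) of 11.91 (SE 0.97, adjusted p = 0.0146). Gbp10, Gbp6, the interferon-inducible GTPase Iigp1, the apolipoprotein L gene Apol6, Tgtp1 and the serpin Serpina3f rose by 11.36, 11.02, 10.73, 9.29, 9.29 and 9.17 on the log2 scale. Control values of these genes lay close to 0, so their folds depend on the pseudocount: with 0.5 and 5 in place of 1, Gbp4 gave 13.63 and 11.87 and Gbp10 gave 11.98 and 9.61. Among the decreases, Ndufa4 had a log2 fold change of -2.60 (SE 0.51, adjusted p = 0.0495), Cav2 of -2.09 (SE 0.32, adjusted p = 0.0344) and Car2 of -1.70 (SE 0.15, adjusted p = 0.0160). Sh3bgrl, the complement inhibitor Cd59a, Vamp7, Lsm5, Tmem70, Vbp1 and Rpa3 followed, with -1.71, -1.63, -1.56, -1.54, -1.52, -1.52 and -1.50. Sh3bgrl, Cd59a and Tmem70 were also higher in CD90pos than in CD90neg control cells (called only with the block). That comparison shares the CD90pos control libraries, so the decreases with IFNg are not independent of it.

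The IFNg pathway itself responded. Irf1, a transcription factor of the interferon response, rose by 4.45 (SE 0.70, adjusted p = 0.0344), and Cd274, which encodes the checkpoint ligand PD-L1, by 7.0 (SE 0.95, adjusted p = 0.0318). The IFNg receptor genes were not called: Ifngr1 had -0.67 (SE 0.32, adjusted p = 0.289) and Ifngr2 -0.86 (SE 0.42, adjusted p = 0.291). Both were lower in the blocked fit (adjusted p = 0.0154 and 0.00377). Of 22 IFNg signalling genes 8 were higher, 14 when adjusted over the list alone, and 0 were lower. They included Batf2 (8.48), the transcription factor Irf8 (6.98) and Socs1 (4.64), a feedback inhibitor of the pathway.

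Antigen presentation genes rose as groups. In MHC class I presentation 13 of 20 genes were higher, and 20 of 20 when adjusted over the list alone, among them the class I transactivator Nlrc5 (5.71), the immunoproteasome subunit Psmb9 (5.54), H2-Q6 (5.02) and H2-Q7 (4.63). In MHC class II presentation 5 of 9 measured genes were higher, 7 when adjusted over the list alone, with H2-Aa at 8.25, the invariant chain Cd74 at 7.92, the class II transactivator Ciita at 7.18 and H2-Eb1 at 5.14. Camera called both lists higher (adjusted p = 2.0e-17 and 5.7e-07), and neither call held with an estimated correlation (adjusted p = 0.215 for each). Among GBP and IRG GTPases, which act against intracellular pathogens, 17 of 20 were higher, 19 when adjusted over the list alone, with a median log2 fold change of 7.70 (camera adjusted p = 9.0e-22, and adjusted p = 0.0818 with an estimated correlation). The IFNg signalling list was called with a median of 2.71 (camera adjusted p = 4.2e-09, and adjusted p = 0.306 with an estimated correlation).

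**Figure D2:**
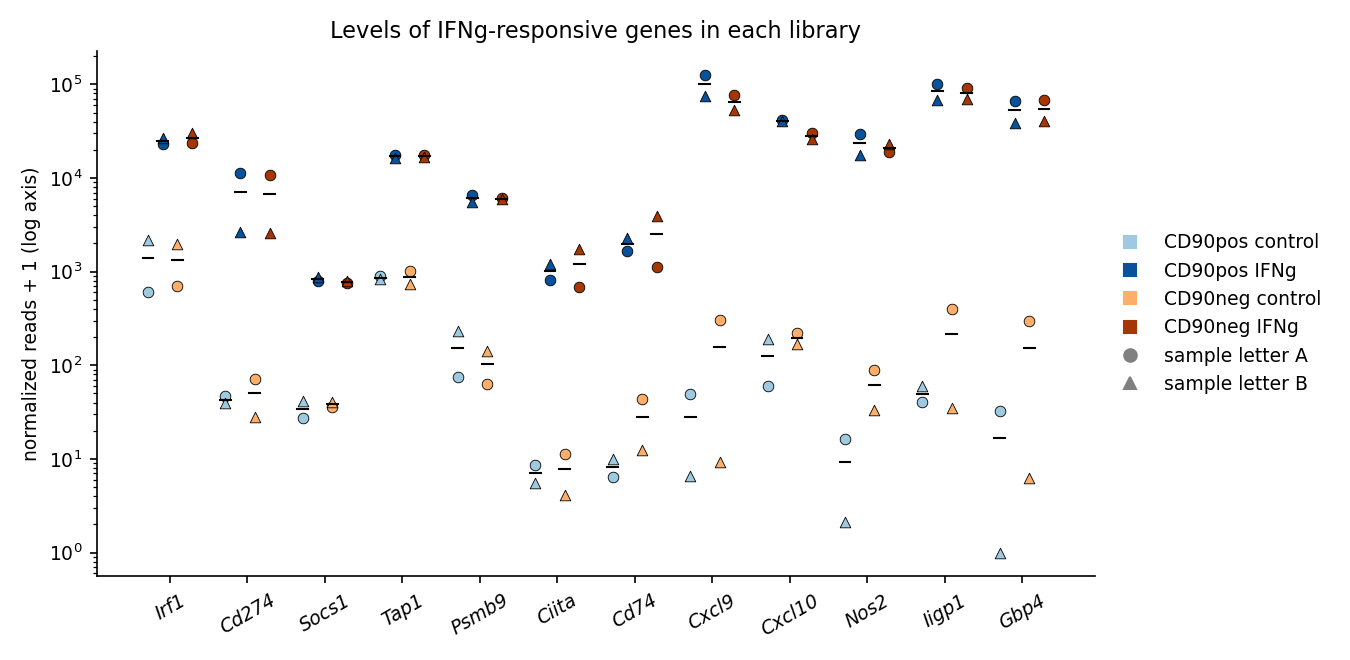
Normalized reads plus 1 (y axis, log scale) are shown for 12 IFNg-responsive genes in each of the 8 libraries, with circles for letter A, triangles for letter B, colours for the groups and black bars for group means. For each gene, every IFNg library lies above every control library, for example Tap1, which lies between 16492 and 17644 in IFNg libraries and between 744 and 1006 in control libraries.

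Antiviral interferon-stimulated genes had a median log2 fold change of 3.26, with 2 of 27 higher (Zbp1, 7.47, and Oasl1, 2.43), 15 when adjusted over the list alone and 25 in the blocked fit (camera adjusted p = 3.5e-10, and adjusted p = 0.601 with an estimated correlation). Of 14 measured chemokines 5 were higher, including Cxcl9, Cxcl10 (8.58), Cxcl11 (7.16) and Ccl2 (2.82), and 7 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.3e-04, and adjusted p = 0.110 with an estimated correlation). In the immune checkpoint and T cell ligand list 2 of 16 were higher, namely Cd274 and the tryptophan-degrading enzyme Ido1 (8.22), and 5 when adjusted over the list alone (camera adjusted p = 0.0253, and adjusted p = 0.601 with an estimated correlation), and the call was lost without CD90pos control A or CD90pos IFNg B (adjusted p = 0.184 and 0.112). Among cell death effectors 5 of 24 were higher, including Zbp1, Casp1 (2.36) and the necroptosis executor Mlkl (1.69), and 13 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 4.1e-05, and adjusted p = 0.110 with an estimated correlation).

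Nuclear genes of oxidative phosphorylation fell in CD90pos cells, with 7 of 25 lower, 13 when adjusted over the list alone, 0 higher and a median log2 fold change of -0.49, and -0.40 and -0.66 within letters A and B. Besides Ndufa4 they included Ndufb3 (-1.08), Cox7a2 (-0.99) and Ndufb8 (-0.94). Camera gave an adjusted p of 3.6e-08, and adjusted p = 0.215 with an estimated correlation. Fold changes in CD90pos cells also followed transcript length: Spearman's coefficient with length was 0.279 across 12947 genes, which are not independent replicates, and the genes of this list are short, with a median of 1818 against 3386 nucleotides for all genes. After removal of the trends with length and GC content in the blocked fit the median was -0.33 (-0.090 and -0.39 within letters A and B) and the list was still called (camera adjusted p = 0.000332, and adjusted p = 0.431 with an estimated correlation). The mitochondrially encoded genes were not called in any comparison in either fit before that removal, and their median of -0.23 in CD90pos cells came from -0.90 in letter A and 0.49 in letter B. After it camera called them in 3 comparisons, with medians of 0.66 in CD90pos cells, -1.0 between control populations and 1.02 for the interaction (adjusted p = 0.0139, 0.0017 and 0.000934, and adjusted p = 0.559, 0.776 and 0.896 with an estimated correlation). These medians were -0.0040, -0.26 and 0.18 within letter A and 1.24, -1.72 and 1.82 within letter B.

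Few genes of the remaining lists were called in CD90pos cells, and camera called none of these lists. The called genes were the stem cell antigen Ly6a (3.34), the only one of the luminal list, Itgb4 (0.87) of the basal list, Sfrp1 (1.60) of the Wnt list, Notch1 (1.49), the glycolytic genes Hk2 (2.19) and Pfkp (1.18), the immediate early gene Zfp36 (1.47) and Il1a (6.46) of the NFkB list, all higher, and S100a4 (-2.21) of the fibroblast and matrix list, which was lower. Median log2 fold changes were 0.38 for luminal, -0.20 for basal, -0.41 for EMT, -0.58 for fibroblast and matrix and -0.75 for the 8 measured leukocyte genes. For the basal, Wnt and immediate early lists the direction of camera differed in sign from the median, and in no called list of any comparison did median, mean and camera differ in sign. Genes of S phase, G2M phase and MYC targets had medians of 0.32, -0.08 and 0.17, with 0 called. Medians were -0.33 for p53 targets, 0.54 for milk genes, -0.15 for stem cell markers, -0.13 for Wnt, -0.38 for Notch, 0.19 for hypoxia and glycolysis, -0.19 for cholesterol synthesis, -0.02 for immediate early, 0.17 for unfolded protein and 0.29 for NFkB targets. In the blocked fit camera also called p53 targets (5 of 17 lower, adjusted p = 0.0168), fibroblast and matrix genes (3 of 20 lower, 0.0305) and luminal genes (6 higher and 1 lower of 20, 0.0454), and with an estimated correlation the adjusted p-values were 0.302, 0.808 and 0.445. Picked by the rule of the blocked fit, Tslp, an epithelial cytokine, had -4.97 (SE 1.58, adjusted p = 0.133, and 0.00208 with the block), and Mmp3 and Cxcl12 had -4.27 and -2.21 (adjusted p = 0.0276 and 0.0203 with the block).

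A fit that leaves out a library has fewer residual degrees of freedom and is unbalanced by letter. The number of genes called in CD90pos cells fell without any single library, including CD90neg libraries, which set only the shared spread here. It was 3 and 2 without CD90pos IFNg A and B, 30 and 101 without CD90pos control A and B, 6 and 19 without CD90neg IFNg A and B, and 112 and 114 without CD90neg control A and B, and 2 genes, Irgm1 and Tap1, were called in every such fit. These were named after their values were seen. With the block, 404 genes were called in every such fit, 284 of them higher. The share of calls that were higher was 50%, against 40.1% (262 of 262 and 392 genes higher and lower) with quantile normalization and 42.8% with median centring.

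IFNg raised the same kind of genes in CD90neg cells, and few genes fell. Among called genes that met the naming rule, Iigp1, the metalloprotease gene Adam33, Tgtp1, Gbp8 and Nos2 had the largest increases. Gbp4 and Cxcl9 rose more than Iigp1 but were not called. Iigp1 went from 398 and 34.3 normalized reads in the control libraries to 91071 and 70339 in the IFNg libraries. Car2 was the only called decrease, from 1772 ± 15.9 to 732 ± 120 normalized reads (SD, n = 2).

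Of 12962 genes 83 were called, 82 higher and 1 lower, and all 83 were among the 537 called in the blocked fit (451 higher, 86 lower). Iigp1 (GRCm38 chromosome 18, 60376029 to 60392627) had a log2 fold change of 9.40 (SE 1.04, adjusted p = 0.0260), Adam33 (chromosome 2, 131050591 to 131063814) of 9.13 (SE 1.14, adjusted p = 0.0352), Tgtp1 of 9.11 (SE 0.74, adjusted p = 0.0155), Gbp8 of 8.99 (SE 0.91, adjusted p = 0.0214) and Nos2 of 8.59 (SE 0.97, adjusted p = 0.0263). In its control libraries Adam33 was at 3.09 and 0 normalized reads, at or under the floor of 3 reads, and with a pseudocount of 0.5 it gave 9.72 and was not called (adjusted p = 0.0701). Gbp6, Olfr56, Batf2, Sectm1b and Apol6 followed with 8.45, 8.17, 8.14, 7.81 and 7.68. Car2 had -1.28 (SE 0.15, adjusted p = 0.0318). Vav3, a guanine nucleotide exchange factor, and the sialyltransferase gene St3gal5 had the next smallest p among the decreases and missed the threshold, with -0.79 (adjusted p = 0.113) and -0.75 (adjusted p = 0.119). Irf1 and Cd274 had log2 fold changes of 4.52 and 6.89 but missed the threshold (adjusted p = 0.0692 and 0.0512) and were called with the block (adjusted p = 0.00177 and 0.000799). Ifngr1 had -0.20 (SE 0.32) and Ifngr2 -0.65 (SE 0.42, adjusted p = 0.0217 with the block).

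The groups that responded in CD90pos cells were also called in CD90neg cells. GBP and IRG GTPases had 12 of 20 higher (19 when adjusted over the list alone), a median of 7.34 and a camera adjusted p of 5.9e-52, and the call held with an estimated correlation (adjusted p = 0.0139, but 0.0814 with the block). MHC class I presentation had 7 of 20 higher (20 when adjusted over the list alone), with Psmb9 at 6.0, Nlrc5 at 5.47 and the peptide transporter genes Tap1 and Tap2 at 4.32 and 4.03 (camera adjusted p = 8.6e-46, and adjusted p = 0.0532 with an estimated correlation). MHC class II presentation had 4 of 9 higher (7 when adjusted over the list alone), with Ciita at 7.33, Cd74 at 6.50, H2-Eb1 at 5.18 and H2-DMb1 at 3.70 (camera adjusted p = 2.9e-17, and adjusted p = 0.0532 with an estimated correlation). IFNg signalling had 3 of 22 higher, namely Batf2, Socs1 (4.35) and Socs3 (2.80), and 15 when adjusted over the list alone (camera adjusted p = 9.0e-22, and adjusted p = 0.0923 with an estimated correlation). Of the antiviral genes 0 of 27 were called, 10 when adjusted over the list alone and 18 with the block, at a median of 3.21 (camera adjusted p = 1.9e-23, and adjusted p = 0.252 with an estimated correlation). Zbp1 (6.76, adjusted p = 0.0683) and Oasl1 (1.97, adjusted p = 0.114) came closest among them.

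Chemokines had 3 of 14 higher, Cxcl10 (7.16), Ccl2 (3.10) and Cx3cl1 (2.09), and 6 when adjusted over the list alone (camera adjusted p = 2.3e-10, which held at an adjusted p = 0.0208 with an estimated correlation, but not with the block, at 0.0823). Checkpoint and T cell ligands had 1 of 16 higher, Ido1 (8.70), and 4 when adjusted over the list alone (camera adjusted p = 3.7e-07, and adjusted p = 0.139 with an estimated correlation). Cell death effectors had 2 of 24 higher, Casp1 (3.41) and Mlkl (1.70), and 13 higher and 1 lower when adjusted over the list alone (camera adjusted p = 3.5e-14, which held at an adjusted p = 0.0139 with an estimated correlation, but not with the block, at 0.0814). Ly6a rose by 3.35 in CD90neg cells (SE 0.27, adjusted p = 0.0155). Camera also called G2M genes lower (median -0.28, adjusted p = 0.00647), oxidative phosphorylation genes lower (median -0.10, 0.0124), hypoxia and glycolysis genes higher (median 0.23, 0.0118) and unfolded protein genes higher (median 0.11, 0.0391), with 0 genes of these lists called and adjusted p-values of 0.815, 0.478, 0.815 and 0.478 with an estimated correlation. Each of these calls also rested on single libraries: G2M was lost without CD90neg control B (adjusted p = 0.357), oxidative phosphorylation without CD90neg control A or IFNg B (0.240 and 0.166), hypoxia without the same libraries (0.116 and 0.498), and unfolded protein without CD90neg control B or IFNg A (0.921 and 0.128). The members with the smallest p missed the threshold, and Hmmr had -0.47 and Ccnb2 -0.29, Ndufa4 -1.49 and Ndufb3 -0.31, Pfkp 1.02 and Hk2 1.45, and Trib3 1.86 and Psat1 0.49. With the block camera also called cholesterol synthesis genes lower (1 of 18, Insig1 at -0.79, adjusted p = 2.8e-06), p53 targets lower (0 of 17, 0.00197) and milk genes higher (3 of 9, 0.00119), with adjusted p-values of 0.424, 0.200 and 0.208 with an estimated correlation. Without single libraries the number of calls was 6 and 9 (CD90pos IFNg A and B), 10 and 12 (CD90neg control A and B) and 3 and 4 (CD90neg IFNg A and B), and Gbp9, Irgm1 and Tap1, named after their values were seen, were called in every such fit. With the block the lowest were 227 and 282 without CD90neg control A and B and 222 and 252 without CD90neg IFNg A and B, and 167 genes were called in every such fit, 163 of them higher.

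Traces of the induced transcripts were present in control libraries and differed between them. Over the 46 genes that rose by at least 6 on the log2 scale in both populations, the median control value was 0.549% of the IFNg value in CD90neg control A, against 0.185% in CD90neg control B, 0.146% in CD90pos control A and 0.293% in CD90pos control B. Cxcl9, for instance, was at 307 normalized reads in CD90neg control A and 8.32 in CD90neg control B.

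The responses of the populations resembled each other across genes. The 2 IFNg effects, which share no library, correlated with Pearson's r = 0.857 and Spearman's rho = 0.597 over 12962 genes, which are not independent replicates, and 70.4% of genes had the same sign. Within letters A and B Pearson's r was 0.835 and 0.769. Over the 547 genes called in either population, the coefficients were 0.977 and 0.931 and 96.2% had the same sign. Of the genes called higher, 81 were shared between the 273 in CD90pos and the 82 in CD90neg cells, against 1.73 for independent lists of these sizes. With the block 425 of 1815 and 451 were shared, against 63.2. Of the genes called lower, 75 of 1763 and 86 were shared with the block, against 11.7.

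**Figure D3:**
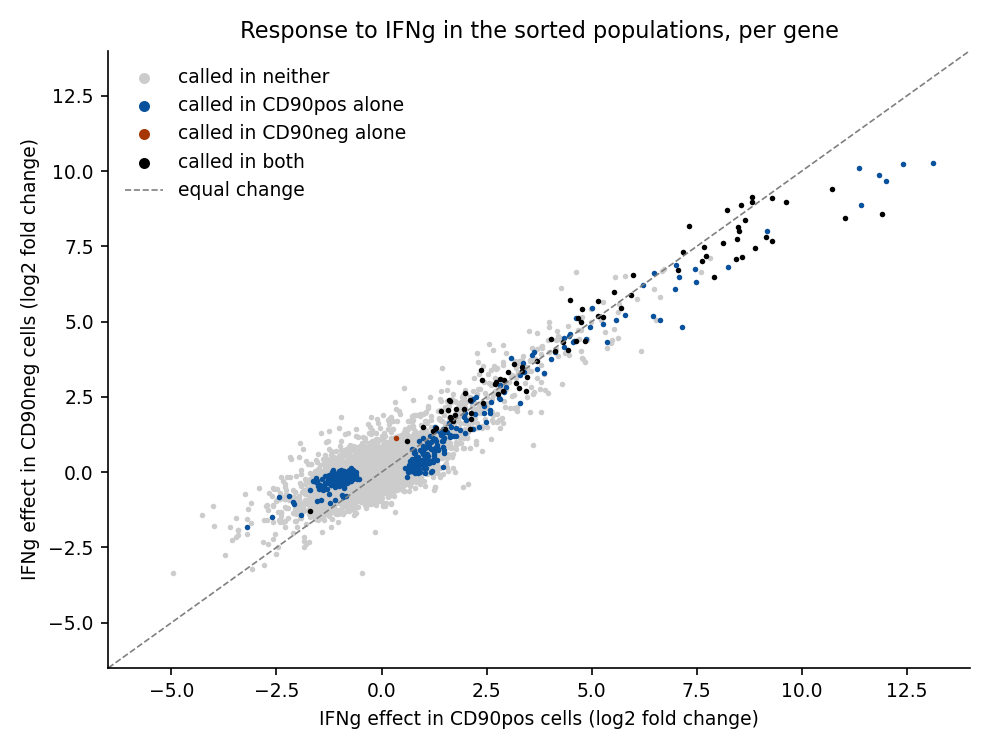
The log2 fold change with IFNg in CD90neg cells (y axis) is plotted against that in CD90pos cells (x axis) for each gene, coloured by where the gene was called, with a dashed line of equal change. The genes that rose most lie near or below the line, for example Gbp4 at 13.12 and 10.26, and most genes called lower in CD90pos cells lie closer to 0 in CD90neg cells. Control values of Gbp4 were 0.440% of the IFNg value in CD90neg control A and 0.0473% in CD90pos control A (0.0127% and 0% in letter B).

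Acta2, the smooth muscle actin of myoepithelial cells, was at 3658 and 235190 normalized reads in CD90pos control A and B and at 696 and 46629 in CD90neg control A and B, a log2 difference of 2.39 and 2.33 within the letters. Tagln, another contractile gene, differed by 2.61 and 2.89. The basal keratin Krt5 differed by 2.04 in letter A and 3.53 in letter B. Ltf, which encodes the secreted protein lactoferrin, was lower in CD90pos cells, at -1.86 and -1.83. These genes were picked in the blocked fit, where the same sign in both letters was a condition, so that agreement is no finding. Other genes of the basal list went the other way in both letters. Itgb4 was at 13346 and 11899 in CD90pos against 19619 and 16938 in CD90neg control A and B. Dst was at 11755 and 11183 against 15644 and 15382.

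With limma without the block 0 of 12962 genes were called, with 1898 at an unadjusted p under 0.05, 0 genes by edgeR and 987 by DESeq2, which gave no adjusted p for 2011 genes. The blocked fit called 1451 genes, 881 higher and 570 lower in CD90pos cells, and 1375 by edgeR and 2531 by DESeq2 with the block. The letters differed far more in Acta2 than the populations did, so that its SE was 3.51 without and 0.12 with the block (adjusted p = 0.868 and 0.00368). Genes picked by the rule in the blocked fit included Krt5 (log2 difference 2.79, adjusted p = 0.0288 with the block), Tagln (2.75, 0.0181), the matrix gene Postn (2.67, 0.0288), Cnn1 (2.37, 0.0288), Acta2, Myh11 (2.36, 0.0288), Ppic (1.89, 0.0181) and Cd59a (1.65, 0.0288), all higher, and Ltf (-1.85, 0.0288) and Msln (-1.78, 0.0355), both lower. In the fit without the block the smallest p among higher genes belonged to Tmem70 (1.33), Sh3bgrl (1.34) and Tnfaip8 (0.95) and among lower genes to Arhgef17 (-0.77), Ttyh3 (-0.79) and Spen (-1.09), all missing the threshold at an adjusted p of 0.173 and called with the block at 0.0288. Irf1, Cd274, Ifngr1 and Ifngr2 differed by -0.036, -0.068, 0.43 and 0.33 and were called in neither fit. Thy1, the sort marker, differed by 5.06 (adjusted p = 0.173, and 0.0288 with the block).

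Among the lists, basal and myoepithelial genes were higher in CD90pos control cells in the blocked fit, with 6 of 21 higher and 1 lower (7 and 1 when adjusted over the list alone) and a camera adjusted p of 0.00841, against 0.787 without the block. The median of 0.52 came from -0.11 in letter A and 1.09 in letter B, so that it was not shared by the letters. EMT genes had 2 of 22 higher with the block, among them Lox (1.78, adjusted p = 0.0365 with the block), and a camera adjusted p of 0.0324. Nuclear oxidative phosphorylation genes had a median of 0.40, with 0.28 and 0.56 within letters A and B. Of these 25 genes 0 were called, 9 when adjusted over the list alone, and 10 were called with the block, with Cox7a2 at 0.92 and Ndufb5 at 0.64 (camera adjusted p = 4.0e-06, and 5.2e-05 with the block). None of these calls held with an estimated correlation (adjusted p = 0.936 for all 3 with the block, and 0.972 without it for oxidative phosphorylation). Also higher with the block were the death receptor gene Fas (1.25, adjusted p = 0.0288) and Cd40 (2.40, 0.0345), both of the checkpoint list, and lower was E2f1 (-0.76, 0.0313) of the S phase list, with 4 of 25 lower. Camera called no other list in control cells in either fit, luminal (median -0.28), fibroblast and matrix (0.31) and leukocyte genes (0.33) included.

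Differences between control populations followed transcript length and GC content, with Spearman's coefficients of -0.294 and -0.399 across 12947 genes, and -0.137 and -0.360 for length within letters A and B. After removal of these trends, 5 of the 1451 blocked calls were left, and 2580 genes had an unadjusted p under 0.05, against 3961 before. Camera then called basal genes (median 0.73, but 0.011 within letter A and 1.38 within letter B, adjusted p = 3.0e-07), EMT genes (0.62, with 0.019 and 1.08 within the letters, 2.3e-04) and fibroblast and matrix genes (0.40, with 0.012 and 0.87, 0.00461) higher. It called mitochondrially encoded (-1.0, with -0.26 and -1.72, 0.0017), S phase (-0.33, with -0.66 and -0.096, 0.00264) and MYC and ribosome biogenesis genes (-0.20, with -0.31 and -0.049, 0.0304) lower. Oxidative phosphorylation genes were no longer called (0.0535), and their median went from 0.40 to 0.051, with -0.13 and 0.27. None of these was called with an estimated correlation (adjusted p = 0.776 for each). The blocked count was 5 and 3 without CD90pos IFNg A and B, 5 and 0 without CD90neg control A and B, 2 and 2 without CD90neg IFNg A and B, and 2468 and 1112 without CD90pos control A and B. The CD90pos control libraries enter both this comparison and the IFNg effect in CD90pos cells, in which the coefficient with length was 0.279.

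**Figure D4:**
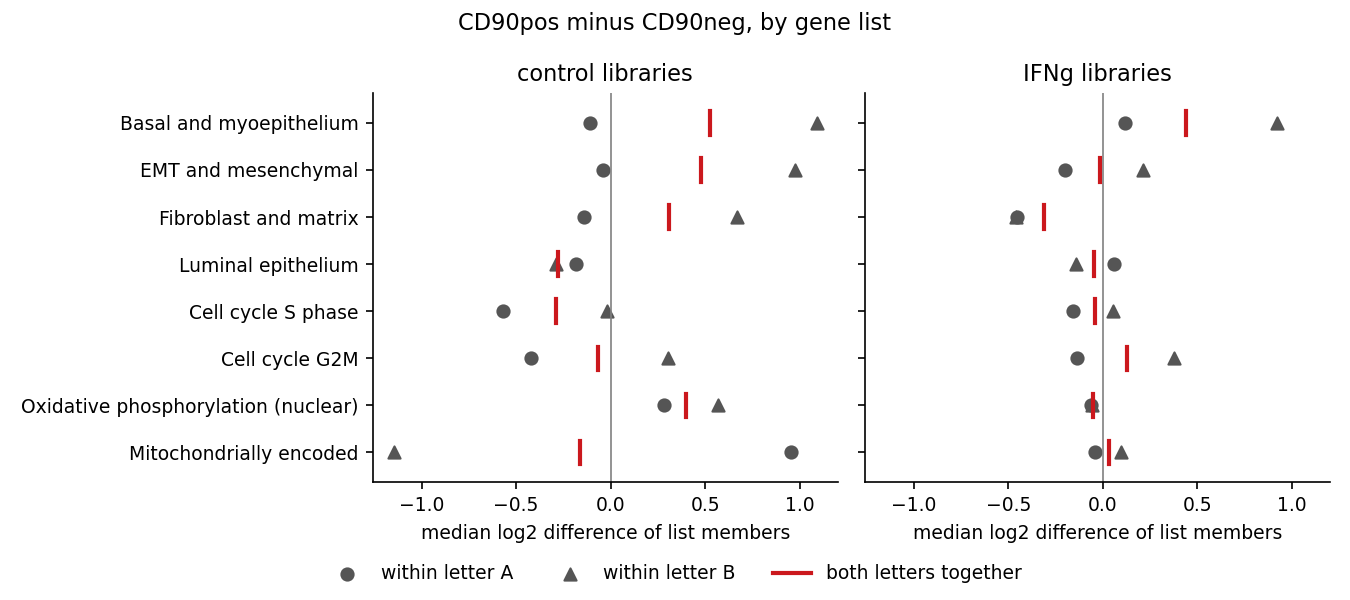
The median log2 difference of CD90pos minus CD90neg cells (x axis) is shown for 8 gene lists (y axis) in control libraries (left) and IFNg libraries (right), within letter A (circles), within letter B (triangles) and for both letters together (red bars). Basal genes in control libraries lie at -0.11 in letter A and 1.09 in letter B, while oxidative phosphorylation genes lie at 0.28 and 0.56.

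Between the IFNg-treated populations the SD of the log2 differences over all genes was 0.26, against 0.52 in control cells. Besides Thy1, at a log2 difference of 5.58 (SE 0.76, adjusted p = 1, and 0.432 with the block), among genes whose groups of libraries did not overlap and whose higher group lay above the median of all genes, the smallest p-values belonged to the endopeptidase gene Mme (0.62) and Adam12 (0.72), higher in CD90pos cells, and to Tnfaip2 (-0.71), the collagen gene Col5a1 (-1.39) and the potassium channel gene Kcnn4 (-0.35), lower in CD90pos cells. Picked by the smallest p in the blocked fit were also Acta2 (0.80, with 0.67 and 0.93 within letters A and B) and the skeletal actin gene Acta1 (1.37, with 1.17 and 1.57), higher in CD90pos cells. Lower there were Ltf (-0.85, with -0.54 and -1.16) and Prl2c3 (-0.83, with -0.84 and -0.82). Krt5, picked from the basal list in that fit, differed by 1.59 (1.09 and 2.08 within the letters). Acta2, Krt5 and Ltf thus had the same sign as in control cells in both letters. All genes named here other than Thy1 missed the threshold with an adjusted p of 1 with and without the block.

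With limma 0 of 12962 genes were called with or without the block, with 17 and 168 at an unadjusted p under 0.05, and edgeR called 0 in both. These 2 limma counts are below a share of 0.05 of the genes, so the test may have been too cautious here. Its spread was shared by the 4 groups: the blocked fit had a median SE of 0.178, against a median absolute log2 difference of 0.086. DESeq2 called 1 gene without and 17 with the block, where it gave no adjusted p for 1508 genes. Irf1, Cd274, Ifngr1 and Ifngr2 differed by -0.10, 0.04, -0.03 and 0.12. Camera called fibroblast and matrix genes lower in CD90pos IFNg cells, with a median of -0.31 over 20 genes and -0.46 within each letter (adjusted p = 1.5e-06), including Thbs2 at -1.65. It called basal genes higher (median 0.44, and 0.12 and 0.92 within letters A and B, adjusted p = 0.00147), with Itgb4 at 0.26 and Dst at 0.39. G2M genes were called higher (median 0.13, but -0.14 within letter A and 0.37 within letter B, adjusted p = 0.0104), with Hmmr at 0.26 and Cenpf at 0.34, and oxidative phosphorylation genes lower (median -0.05, adjusted p = 0.0237, and 0.0827 with the block), with Atp5o at -0.14 and Sdhc at -0.11. Of these lists 0 genes were called, also 0 when adjusted over the list alone without the block (4 basal and 2 fibroblast and matrix genes with it), and the camera calls did not hold with an estimated correlation (adjusted p = 0.995 for each). Single libraries decided each call. Fibroblast and matrix was lost without CD90pos IFNg A or CD90neg IFNg B (adjusted p = 0.600 and 0.485). Without CD90pos IFNg B or CD90neg IFNg A basal was lost (0.113 and 0.885), G2M (0.113 and 0.162) and oxidative phosphorylation (0.558 and 0.757). G2M was also lost without CD90neg IFNg B (0.135). Without CD90pos IFNg B the direction of the basal and G2M lists was also reversed. The lists of IFNg-induced genes had medians between -0.14 and 0.12 and were not called.

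Whether the populations responded differently to IFNg was tested by the interaction. With limma 0 of 12962 genes were called, with 826 at an unadjusted p under 0.05 without and 2154 with the block. On simulated counts the fit without the block recovered 0% of genes changed by 1 or by 2 on the log2 scale. The blocked fit recovered 17% and 81%. The 0 calls therefore do not show that the responses were equal. Counts were 0 by edgeR in both fits and 171 and 583 by DESeq2, which gave no adjusted p for 6534 and 3518 of the genes. Without the block the smallest p-values belonged to the chromatin regulator Ep400 (0.89), Spen (1.19) and Ubap2 (0.90), which had the more positive IFNg effect in CD90pos cells, and to Ndufv2 (-0.97), a complex I subunit, Tmem70 (-1.14) and the splicing factor Snrpe (-1.16), which had the more negative effect there. These missed the threshold (adjusted p = 0.783, and 0.179 with the block). In the blocked fit the genes with the smallest p included Myh14 (1.26), Slc25a48 (0.92), Acta2 (-1.56), Sat1 (-1.12) and Tagln (-1.98). These missed the threshold too (adjusted p = 0.179 with the block). They had the same sign in both letters, but a small p in the blocked fit favours such genes, so this adds no support. Ndufv2 went from 3877 ± 126 to 1854 ± 53.1 normalized reads in CD90pos cells and from 2175 ± 114 to 2033 ± 9.49 in CD90neg cells (SD, n = 2). Interaction values of Irf1, Cd274, Ifngr1, Ifngr2 and Thy1 were -0.07, 0.11, -0.47, -0.21 and 0.52, each with an adjusted p of 1.

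Nuclear oxidative phosphorylation was the only list that camera called for the interaction without the block. Its median was -0.47 (-0.42 and -0.59 within letters A and B), with 0 of 25 genes called, 6 lower when adjusted over the list alone and 10 with the block (adjusted p = 3.0e-08, and 7.9e-07 with the block), and Ndufb5 (-0.69) and Uqcrc2 (-0.75) had the smallest p without the block. With an estimated correlation the adjusted p was 0.790 without and 0.973 with the block. Interaction values also followed transcript length across genes, with Spearman's rho = 0.360, and after removal of the trends with length and GC content the median was -0.082, with 0.097 and -0.26 within letters A and B (camera adjusted p = 0.0119, blocked fit, and adjusted p = 0.896 with an estimated correlation). After that removal camera also called fibroblast and matrix (-1.09, 2.9e-08), EMT (-0.55, 0.000577), basal (-0.49, 0.000934), S phase (0.35, 0.0119) and mitochondrially encoded genes. None of these lists was called with an estimated correlation (adjusted p = 0.896 for each). With the block, fibroblast and matrix genes were called too, at a median of -0.98 (-0.53 and -1.61 within letters A and B), with 0 of 20 genes called and 2 lower when adjusted over the list alone (adjusted p = 0.00227, against 0.108 without the block, and adjusted p = 0.973 with an estimated correlation), and S100a4 (-1.42) and Thbs2 (-1.58) had the smallest p in the fit without the block. The lists of IFNg-induced genes were not called for the interaction, with medians from -0.30 for checkpoint ligands to 0.51 for GBP and IRG GTPases. The letters did not share the latter: after removal of the trends it was 0.61, with 1.8 within letter A and -0.43 within letter B.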

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

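Tests of Thy1 and of the basal list after removal of the trends were chosen only after the result was seen, and the edgeR, DESeq2, length and GC content and blocked leave-one-out fits were added after the data were examined.

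For the interaction camera called the nuclear oxidative phosphorylation list, with a median of -0.47 over 25 genes in both fits (camera adjusted p = 3.0e-08 without and 7.9e-07 with the block). It called the fibroblast and matrix list in the blocked fit alone, with a median of -0.98 over 20 genes (camera adjusted p = 0.00227, and 0.108 without the block) and -1.09 after removal of trends with transcript length and GC content (camera adjusted p = 2.9e-08, and 0.896 with an estimated correlation). Limma called 0 genes of either list for the interaction in both fits, adjusted over all genes (6 oxidative phosphorylation genes without the block and 10 with it, and 0 and 2 fibroblast and matrix genes, when adjusted over the list alone). Of all 12962 genes it also called 0, with 826 and 2154 at an unadjusted p under 0.05, while edgeR called 0. On simulated counts limma without the block recovered 0% of genes with an interaction of 1 or 2 on the log2 scale, and 17% and 81% with it. Its 0 calls therefore do not show that the responses were equal. DESeq2 called 171 without and 583 with the block but gave no adjusted p for 6534 and 3518 genes, so that it adjusted over fewer genes. With an estimated correlation neither list was called before that removal (adjusted p = 0.973 for each with the block, and 0.790 for oxidative phosphorylation without it).

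In the blocked limma fit 1451 genes differed between CD90pos and CD90neg control cells, against 0 between IFNg-treated cells, where 168 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 17. Both comparisons used 1 spread shared by the 4 groups, with a median SE of 0.178. Median absolute log2 differences were 0.31 between control and 0.086 between IFNg-treated populations. The shared spread may be too large for the IFNg libraries, so the 2 counts do not compare the populations on equal terms. A failed sort in the IFNg arm was excluded by Thy1, which was 39.4-fold (A) and 60.1-fold (B) higher in CD90pos than in CD90neg IFNg libraries. A trend with transcript length or GC content may account for most of the genes called in control libraries: after its removal 5 of the 1451 calls were left, and the median absolute log2 difference of these genes went from 0.69 to 0.37 while their median SE went from 0.132 to 0.122, so that the differences shrank and their SE did not grow. Removal takes away any difference that follows length or GC content, whatever its source, so this does not show that the trend made the calls. After it 2580 genes still had an unadjusted p under 0.05, against 3961 before. Such a trend may also account for part of the oxidative phosphorylation interaction, whose median came to -0.082 (0.097 within letter A, -0.26 within letter B), within the bound of 0.1 set beforehand, although camera still called the list (adjusted p = 0.0119, and 0.896 with an estimated correlation), while for the basal list, at 0.73 after removal (0.011 within letter A, 1.38 within letter B, camera adjusted p = 3.0e-07, and 0.776 with an estimated correlation), the letters differ too much to decide. Whether 1 library of the control arm made the calls stays open, because 5 and 0 calls were left without CD90neg control A and B but also 2 to 5 without any 1 IFNg library, while 2468 and 1112 were made without CD90pos control A and B, and a difference between the control populations that IFNg treatment removes stays open, since its test, the interaction, called 0 genes by limma (826 at an unadjusted p under 0.05, and 2154 with the block) and edgeR but 171 and 583 by DESeq2, over fewer genes.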

How the results depend on the processing

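Fits with edgeR and DESeq2, all other fits with the block besides the plain blocked one, and the correction for transcript length and GC content were chosen only after the result was seen. Leaving out a library assumes that the lone sample of its group varies like the other groups, and without the block such a fit is unbalanced by letter. Genes with few reads in control libraries have folds that depth and pseudocount limit. Except where an explanation is given, the cause was not tested.

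The 546 calls for IFNg in CD90pos cells became 94 without the trend of the variance, 3578 with the block, 10 with only the 4 libraries compared, where fewer samples set the spread, 320 with a required 2-fold change, 2042 with DESeq2 and 2 to 114 without single libraries. The blocked count became 2138 after correction for length and GC content (887 higher, 1251 lower), 1198 with a required 2-fold change and 460 to 4035 without single libraries. The 83 calls in CD90neg cells became 537 with the block, 8 with only 4 libraries, 367 with DESeq2 and 3 to 80 without single libraries, and the blocked count became 957 with DESeq2 and 222 to 698 without single libraries. For the control populations 0 (1898 at an unadjusted p under 0.05, edgeR 0) became 1451 with the block and 987 with DESeq2 and stayed 0 without single libraries, and the blocked 1451 became 2531 with DESeq2, 5 after correction for length and GC content, 191 with a required 2-fold change and 0 to 2468 without single libraries. For the IFNg-treated populations 0 became 1 with DESeq2 and 17 with DESeq2 and the block, and for the interaction 171 and 583 (DESeq2 gave no adjusted p for 1508 genes in the fit with 17 calls and for 6534 and 3518 in these), while limma (17 and 168, and 826 and 2154, at an unadjusted p under 0.05 without and with the block) and edgeR gave 0. Other settings kept each count within 1.5 times, and other scalings shifted the median of all genes by less than 0.1.

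Of 140 tests of gene lists camera called 27, against 3 with an estimated correlation, 13 with fry in one direction, 48 after correction for length and GC content with the block, and 31 to 56 without single libraries. The block gave 35, quantile normalization 29 and fry in either direction 20, and of the 27 the block ended only that of oxidative phosphorylation between IFNg-treated populations (adjusted p = 0.0827). In the comparison of IFNg-treated populations the adjusted p was 0.113 for G2M and for basal genes without CD90pos IFNg B, where the direction reversed, with ranges over the libraries left out of 7.9e-08 to 0.162 and 3.0e-10 to 0.885. The correlation of the IFNg effects across genes was 0.857, and 0.679 to 0.771 without single libraries.

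Over the named genes and comparisons, 130 kept direction and side of the threshold with the block, and 42 passed it only then, while no other call of a named gene changed with the block. With DESeq2 135 kept both and 36 came to pass, with edgeR 156 kept both and 15 were lost, without the trend 39 were lost, with only 4 libraries 76, with quantile normalization 8, with a pseudocount of 0.5 3, with median centring and a robust prior 2 each, and with a filter at 50 1. With single libraries left out, 846 values kept both, 490 lost and 2 gained the call, and 38 reversed in sign, all in genes and comparisons not called in the fit without the block (lowest adjusted p = 0.824, limma), of which Tagln, Cnn1, Acta2, Myh11 and Ltf between control populations were called with it. In CD90neg cells Ifngr1 ranged from -0.44 to 0.037. Between control populations the ranges were -0.034 to 0.69 for Ifngr2, -0.96 to 0.89 for Irf1, -0.75 to 0.61 for Cd274, -0.11 to 5.61 for Tagln, -0.28 to 5.03 for Cnn1, -0.67 to 5.40 for Acta2, -0.68 to 5.40 for Myh11 and -4.84 to 1.14 for Ltf, and there Irf1 was also 0.066 with edgeR and 0.062 with DESeq2. Between IFNg-treated populations they were -0.31 to 0.25 for Ifngr1, -0.23 to 0.47 for Ifngr2, -0.28 to 0.078 for Irf1, -1.01 to 1.10 for Cd274, -8.1e-05 to 0.52 for Hmmr and -0.038 to 0.71 for Cenpf. For the interaction they were -0.68 to 1.72 for Thy1, -0.57 to 0.15 for Ifngr2, -0.99 to 0.86 for Irf1 and -0.94 to 1.17 for Cd274.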

Other observations

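Apart from the count of other splits of the libraries, the tests reported here were chosen only after the result was seen, as were the genes named.

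Libraries with the letter B differed from those with the letter A across all 4 groups, and the labels do not say what the letters stand for. The letters were compared by a limma fit of the letter alone, without population or treatment. The 4 libraries of a letter come from the 4 different groups, so SDs and p-values here measure the spread across groups and not between replicates. Cholesterol synthesis genes were higher in B libraries in 15 of 18 cases and lower in 0 (limma, adjusted p under 0.05, median log2 difference 1.14, camera adjusted p = 6.1e-10), for example Hmgcs1 at 11653 ± 1599.8 against 4353 ± 808 normalized reads (SD, n = 4). Luminal genes were higher in 15 of 20 cases and lower in 1 (median 1.15, camera adjusted p = 1.8e-06), with Elf5, a regulator of the luminal lineage, at 959 ± 506 against 16.9 ± 7.96, and basal genes were higher in 13 of 21 and lower in 1 (median 2.09, camera adjusted p = 5.6e-06), with Krt14 at 22014 ± 6480.2 against 5269 ± 1700.2 (SD, n = 4). NFkB targets were higher in 11 of 21, G2M genes in 11 of 25, S phase genes in 8 of 25 and hypoxia genes in 5 of 22, with 0 lower in each (camera adjusted p = 1.3e-05, 2.7e-05, 1.8e-05 and 0.00119). Of p53 targets 8 of 17 were lower and 2 higher in B libraries (camera adjusted p = 0.0187), and of antiviral genes 1 of 27 was higher (camera adjusted p = 0.0043). None of these lists was called with an estimated correlation, where the lowest adjusted p was 0.390.

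Between the letters 2693 of 12962 genes differed (1518 higher in B, 1175 higher in A), and 1873 to 2897 did without single libraries. Among the 35 splits of the 8 libraries into 4 and 4, only 1, the split by letter, gave as many, and the highest other was 498, for control against IFNg libraries, while the 8 splits that take 1 library of each group, of which the highest other was 0, are too few for a share under 0.05, and a trend with transcript length or GC content was excluded, since such terms explained 0.661% of the variance of the difference across genes. There were 19 genes at 100 or more normalized reads in all 4 libraries of one letter and at 10 or less in all 4 of the other, with Tlx1 and Erdr1 present in A only and 17 genes, for example Clca3a2 and Tfap2b, in B only. This count lies between the 5 or fewer set for a single culture prepared in technical batches and the 20 or more set for tumour cultures of different origin, so that the count alone leaves both open, and these bounds were set after the data were seen. The size of single differences argues against preparation alone, without a test of it: Tlx1 was at 1090.2 to 1660.2 in A and 0 to 1.1 in B libraries, Xist at 26.7 to 48.2 in A and 4586 to 15252 in B libraries, and Gbp2b in IFNg libraries at 55603 and 43682 in A and 100.1 and 73.2 in B.

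Control libraries held traces of IFNg-induced transcripts, with medians over the 46 genes that rose by at least 6 on the log2 scale in both populations (blocked fit) of 0.146% (CD90pos A), 0.293% (CD90pos B), 0.549% (CD90neg A) and 0.185% (CD90neg B) of the IFNg level. Carry-over of a fixed share of IFNg-treated material was excluded as the whole source in CD90pos control A, CD90pos control B and CD90neg control B, where the largest share that every gene allows was only 0.390, 0.0603 and 0.205 of the median trace. In CD90neg control A it was 0.857 of the median, so that carry-over may account for the traces there. Index switching shared by the A libraries could not be decided, because the median trace of CD90neg control A was 3.75 times that of CD90pos control A, between the bounds of 2 and 5 set for it. No biological explanation, such as a low level of IFNg in control cultures, was tested.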
